A study of Mus musculus with 6 samples.

How the data were processed

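Methylation at CpGs was measured by whole-genome bisulfite sequencing of LSK cells sorted from mouse bone marrow, in 3 WT and 3 Tet2/3 DKO samples. Per the labels, DNA was sheared, adapter-ligated with a TruSeq Nano kit, treated with bisulfite and then amplified. Bisulfite turns unmethylated cytosine into uracil and leaves 5-methylcytosine and 5-hydroxymethylcytosine unchanged, so a level is the sum of these marks. Tet enzymes make the second from the first, so their loss can move a level less than it moves either mark.

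The authors deposited a single table with the count of methylated reads and the count of all reads at each CpG in each sample, neither normalised nor pooled over replicates. BSMAP 2.74 and the mouse build mm9 are named in the submitters' processing notes. The filters on reads and calls, the removal of PCR duplicates and the trimming of read ends are not given in the sources used here. Duplicate reads would make the counting error larger than the read numbers imply, and the model below estimates that excess from the spread between replicates. The table was checked: 0 CpGs were listed more than once, 0 rows were of another width than 2 bp, and 0 values had more methylated than total reads. There were 0 columns of other samples. Coordinates are given from 1, on mm9.

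A level is methylated reads over all reads, in percent. Reads were summed over the CpGs of non-overlapping 1 kb windows and 1 Mb bins. A read is thus counted at each CpG it covers, and the number of separate reads is smaller where CpGs are dense. A window was tested if it lay on an autosome and had at least 3 CpGs and 20 reads in every sample, which held for 774732 windows, 33.2% of the autosomal windows with a CpG. A bin needed 1000 reads in every sample. Each window was tested with a quasi-binomial logistic model of the 2 groups on methylated and unmethylated reads. The dispersion was moderated across windows by the method of limma's squeezeVar, with a floor of 1, and the deviance was tested by an F test. P-values were adjusted by the Benjamini-Hochberg method. A call needed an adjusted p under 0.05 and a difference between group means of at least 10 percentage points. For the 1 Mb bins no minimum difference was set. Single values per sample were compared with two-sided exact permutation tests, which with 3 samples against 3 cannot go below p = 0.1. P-values of the exact permutation tests refer to the spread between these samples. In the test of a 1 kb window, the prior shared by all windows (23.7 degrees of freedom) outweighed the spread within that window. The samples of a group can therefore differ widely in a called window. Fisher's exact test on pooled reads, used as an alternative, takes no account of the spread between samples.

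Windows were classed by their mean level over all 6 samples, with limits at 10, 50 and 80%, and by the CpGs listed per kb. Counting error was larger in WT, so this choice can favour windows with low WT values by chance. The classing by level was therefore repeated after the data were seen. For this, every window was thinned to equal reads in all samples. Its reads were split at random into a part for classing and a part for measuring. Called windows of the same direction at most 1 kb apart were merged. The rule for named regions was the 10 regions in each direction with the largest difference among those of at least 2 windows whose samples did not overlap between groups; 10 higher regions and 0 lower met it. Other regions named in the text, the 1 Mb bins included, were chosen after their values were seen. Lost segments were sought as windows with at least 10 reads in every WT sample and a share of the autosomal reads at least 80% lower in every DKO sample than in every WT sample; the share of autosomal reads took the place of the sample median named in the plan. The groups, tests, named regions and most alternatives were fixed before the data were examined.

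Replicates of a group were compared by their read counts per 1 Mb bin, and no pair agreed within sampling noise. DKO replicate 2 differed most in coverage. Its chi-square per degree of freedom was 117 and 81.3 against DKO replicates 1 and 3, and it was 11.8 to 23.0 for the other pairs. Pearson's r over tested windows was 0.898 to 0.913 within groups and 0.881 to 0.899 between groups. The share of CpGs with at least 10 reads was 2.52% ± 0.178 in WT and 9.63% ± 4.84 in DKO (SD, n = 3), so counting error was smaller in the DKO levels.

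The test was run on simulated data with the depths and levels of the real windows, and with noise drawn from the dispersion prior that the test fitted to them. With 20000 of 774732 windows raised by 30 points, it called 45.9% of them and 0.0123% of the unchanged windows, and limma on log2 ratios called 0. With 200 windows changed by each of 10, 20 and 30 points, either way, both called 0 of them. With no changed window both called 0. The simulated noise followed the test's own model, and changed windows were taken from intermediate levels. These rates therefore do not measure the false calls or the power of the test on the real data.

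Alternatives were leaving out each sample, other read minima and minimum differences, 500 bp and 5 kb windows, limma on log2 ratios with 1 read added to each side, Fisher's exact test on pooled reads, centring on the global level of each sample, and the replicate number as a block. Gene lists and genomic context were planned but not run, because no mm9 annotation was used here, and no coordinates were converted. The work used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6, numba 0.67.0, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.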

Results

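Genome-wide CpG methylation was measured by whole-genome bisulfite sequencing in mouse LSK cells, the lineage-negative, Sca-1-positive, c-Kit-positive fraction of bone marrow that holds blood stem cells and early progenitors. Wild-type cells (WT, 3 samples) were compared with cells lacking Tet2 and Tet3 (Tet2/3 DKO, 3 samples), the genes of 2 enzymes that oxidise 5-methylcytosine. The labels call the samples biological replicates, without saying whether each came from a single animal. The question was how loss of both enzymes changes DNA methylation in these cells. The table listed 20451903 CpGs. The WT samples held 70917633, 72747248 and 70815948 read calls at CpGs, and the DKO samples held 101957758, 111763872 and 83560585. The mean depth was 3.47, 3.56 and 3.46 reads per CpG in WT and 4.99, 5.46 and 4.09 in DKO. Each single CpG was therefore measured coarsely, and read calls were summed over 1 kb windows, where the median was 52 calls per tested window and sample. Reads given below for windows, bins, segments and regions are such calls, counted at each CpG that a read covers.

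The DKO samples had no reads over a segment of chromosome 3, and none or few over a segment of chromosome 6. On chromosome 3, from 133132001 to 133136000 (mm9), the WT samples had 109, 165 and 136 reads and each DKO sample had 0. On chromosome 6, from 83352001 to 83355000, the WT samples had 208, 231 and 169 reads and the DKO samples had 14, 0 and 0. Over these segments and their edges, 44 successive CpGs on chromosome 3 (133131848 to 133136995) and 50 on chromosome 6 (83353141 to 83355177) had no read in any DKO sample. A count of 0 allows up to 1.34%, 1.22% and 1.63% of the mean autosomal depth in the 3 DKO samples on chromosome 3, and up to 1.18%, 1.07% and 1.44% on chromosome 6. These limits cover counting error only, and take calls at neighbouring CpGs as independent although a read can cover several. The stretches were delimited by the absence of DKO reads, so their counts of 0 were fixed by that choice and the limits are too low. Over the whole chromosome 6 segment DKO replicate 1 had 0.0387 times the mean autosomal depth. The RefSeq gene table (GRCm38.p6) places Tet2 on chromosome 3 and Tet3 on chromosome 6; no mm9 gene annotation was used here, so the position of the segments within genes is not given. Among 1463837 windows scanned, 27 lost at least 80% of their relative depth in every DKO sample, and these were the 2 runs of adjacent windows among them. The mirror scan found 45 windows lost in every WT sample, with 0 adjacent pairs. Flanking sequence had depths between 0.819 and 1.13 times the autosomal mean in all 6 samples.

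**Figure D1:**
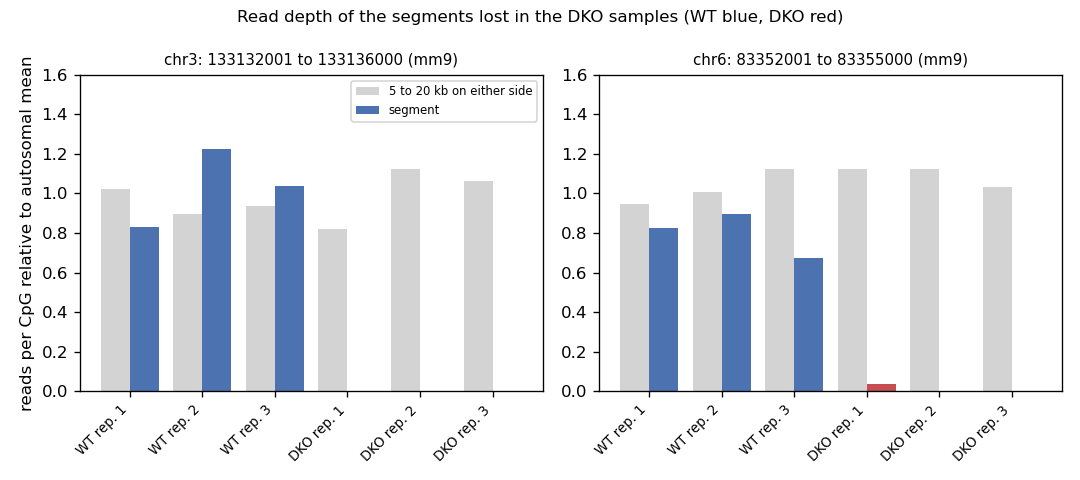
Read depth of the segments on chromosomes 3 and 6 in each sample, as reads per CpG relative to the autosomal mean of that sample (coloured bars, WT blue and DKO red), beside the flanking sequence (grey bars). The DKO bars are at 0 on chromosome 3, and on chromosome 6 only DKO replicate 1 has a bar, at 0.0387.

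Windows of intermediate methylation were higher in the DKO cells. Windows with a mean level of 10 to 50% had 27.7% ± 0.118 in WT and 33.9% ± 0.416 in DKO (SD, n = 3 each; 35171 windows), a difference of 6.24 points. Windows at 50 to 80% had 66.3% ± 0.103 and 72.7% ± 0.321 (79655 windows), a difference of 6.45 points. The difference was smaller at both ends of the scale. Windows below 10% had 3.12% ± 0.178 in WT and 3.98% ± 0.0737 in DKO (21444 windows), and windows at 80% or more had 91.5% ± 0.118 and 92.3% ± 0.356 (638462 windows). With windows classed by WT replicate 1 alone, DKO exceeded the mean of the other WT samples by 1.71, 7.41, 4.52 and 0.738 points from the lowest class to the highest. With windows classed by one part of equally thinned reads and measured by the other, a setting added after the data were seen, the middle classes differed by 6.06 and 6.03 points. In each of the 4 classes all 3 DKO samples lay above every WT sample, with a two-sided exact permutation p = 0.1, the smallest that 3 samples against 3 allow. Reads from the unmethylated mitochondrial genome, a measure of incomplete conversion, were called methylated at 1.28% ± 0.0797 in WT and 1.71% ± 0.170 in DKO (SD, n = 3). The groups thus differed by 0.437 points in this measure and by 0.856 points in windows below 10%.

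**Figure D2:**
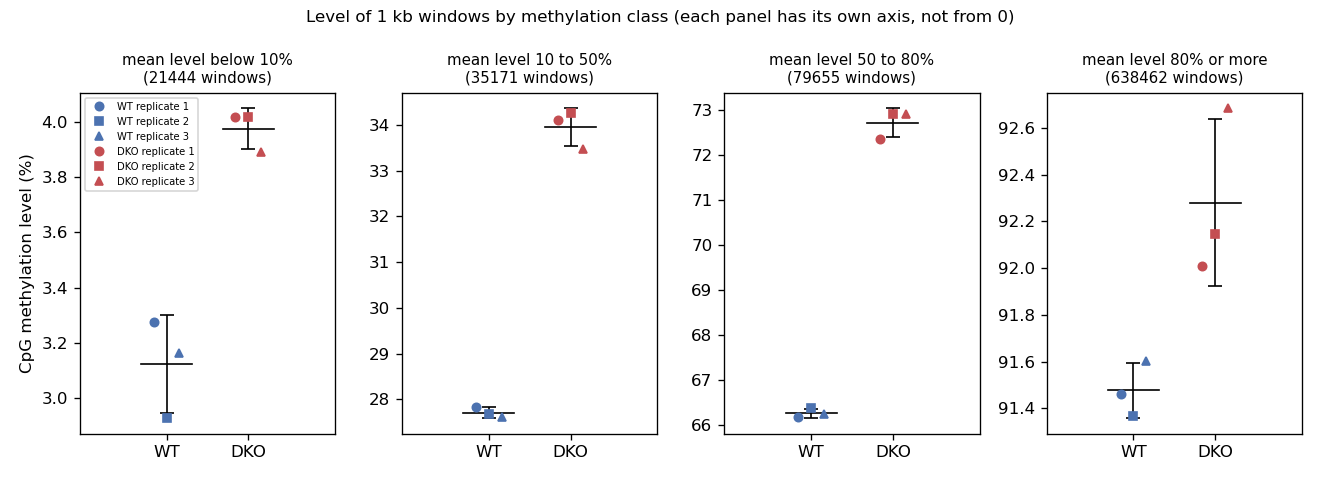
CpG methylation level (%) of 1 kb windows in each sample, in 4 panels by the mean level of the window over all samples. Symbols are samples, horizontal lines are group means and bars are the SD (n = 3). The 3 DKO samples lie above the 3 WT samples in each panel, by 6.24 and 6.45 points on average in the middle panels.

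The level over all autosomal CpGs was close in both groups. It was 80.8% ± 0.314 in WT and 81.6% ± 0.826 in DKO (SD, n = 3 each), a difference of 0.787 ± 0.510 points (SE; two-sided exact permutation p = 0.3), with DKO replicate 2 at 80.7%, inside the WT range. It was 1.25 points without DKO replicate 2 and 0.458 points without DKO replicate 3. The DKO mean was higher on all 19 autosomes, by up to 1.28 points, but on 0 of them did all 3 DKO samples lie above every WT sample. The X chromosome had 82.4% ± 0.296 in WT and 82.5% ± 0.885 in DKO (SD, n = 3; exact permutation p = 1). The Y chromosome had 72.8% ± 0.717 and 72.7% ± 1.41 (SD, n = 3; exact permutation p = 0.8). Over the 10202440 CpGs with a read in every sample the difference was 0.882 points, and with the same CpG weights in all samples, a setting added after the data were seen, 0.992 points; in both, all 3 DKO samples lay above every WT sample (exact permutation p = 0.1, n = 3 each). The difference was 1.48 points, with the same separation (exact permutation p = 0.1), over the 218834 CpGs with at least 5 reads in every sample, and 0.142 points (exact permutation p = 0.7) over the 21112 with at least 10.

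Single windows that passed the test were almost all higher in DKO. Of 774732 autosomal windows tested, 3798 were higher and 56 lower (quasi-binomial test with limma-type moderation of the dispersion, adjusted p < 0.05 and at least 10 points), so 98.5% of the calls were gains. In the windows called higher the median level was 44.8% in WT and 79.5% in DKO, with a median difference of 30.1 points, and 3737 of them had all 3 DKO samples above all 3 WT samples. The windows called lower had a median difference of -20.3 points, with median levels of 42.9% and 17.8%. With the same CpG weights in all samples the median of the 55 of them with enough shared CpGs was -9.30 points. The groups were apart in 22 of these, against 49 with each sample's own reads. Chromosome 11 had the highest rate, 6.93 windows called higher per 1000 tested, and chromosome 9 the lowest, 3.97. Across all tested windows, 9.05% had every DKO sample above every WT sample and 3.75% the reverse, where chance order gives 5% each. On the X chromosome 0 of 3202 windows were called by the same test, and 277 passed an unadjusted p of 0.05. The X had 0.435 times the autosomal depth in WT and 0.426 times in DKO, and its windows were adjusted apart. Of its tested windows 56.4% had a higher DKO mean, against 58.2% of the autosomal windows. The absence of calls therefore does not show that the X was spared. The number of calls depended on each library, being 435, 559 and 491 without WT replicates 1, 2 and 3, and 361, 29 and 749 without DKO replicates 1, 2 and 3. It also depended on the settings. Limma on log2 ratios gave 0 calls (61094 windows past an unadjusted p of 0.05, 48611 of them higher). The replicate number as a block gave 0 (48161 past an unadjusted p of 0.05, 37721 of them higher), and 500 bp windows gave 0 (41408 past it). Reads thinned to equal depth, added after the data were seen, gave 0 (65155 past it). Minima of 10 and 40 reads gave 304 and 271 calls, and Fisher's exact test on pooled reads gave 50074.

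Neighbouring windows called higher formed 3593 regions, of which 181 held at least 2 windows, and the 56 windows called lower were all isolated. The largest gain among regions of at least 2 windows was on chromosome 11, 83462001 to 83464000 (mm9, 18 CpGs, 63 to 117 reads per sample), from 18.0% ± 4.55 to 75.1% ± 2.46 (SD, n = 3; smallest adjusted p = 0.00156 by the quasi-binomial test with limma-type moderation). On chromosome 8, 35911001 to 35913000 (68 to 166 reads) went from 36.1% ± 0.667 to 84.7% ± 6.90. On chromosome 10, 5725001 to 5728000 (151 to 272 reads) went from 36.9% ± 10.9 to 83.0% ± 3.63. Chromosome 3 held a pair of these regions. The region at 97767001 to 97770000 (47 to 143 reads) went from 28.7% ± 15.8 to 74.7% ± 6.67, with WT samples at 12.8%, 28.9% and 44.3%. The region at 96366001 to 96368000 (71 to 199 reads) went from 23.6% ± 5.47 to 67.7% ± 4.93. On chromosome 7, 146554001 to 146556000 (68 to 189 reads) went from 26.6% ± 11.4 to 71.2% ± 8.50. The CpG-densest of the 10 regions was on chromosome 11, 120047001 to 120049000, with 102 CpGs and 212 to 540 reads per sample, and went from 13.1% ± 3.53 to 57.1% ± 1.84. The one of the 10 with the most called windows was also on chromosome 11, where 5 windows from 90240001 to 90246000 (269 to 516 reads) went from 29.6% ± 8.71 to 73.5% ± 0.360. Chromosome 13 held the other two, at 102460001 to 102466000 (185 to 413 reads), from 18.3% ± 5.67 to 61.4% ± 8.64, and at 40985001 to 40989000 (91 to 167 reads), from 14.3% ± 3.69 to 57.2% ± 7.79. In all 10 regions every DKO sample lay above every WT sample, which was a condition of their choice and fixes the sign when a sample is left out. The difference was then 38.1 to 59.7 points over the 10 regions and 6 omissions. The number of these regions that still held a called window was 5, 8 and 5 without WT replicates 1, 2 and 3. It was 4, 1 and 8 without DKO replicates 1, 2 and 3. With limma on log2 ratios it was 0, with the replicate number as a block also 0, and 3 with minima of 10 and of 40 reads alike.

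**Figure D3:**
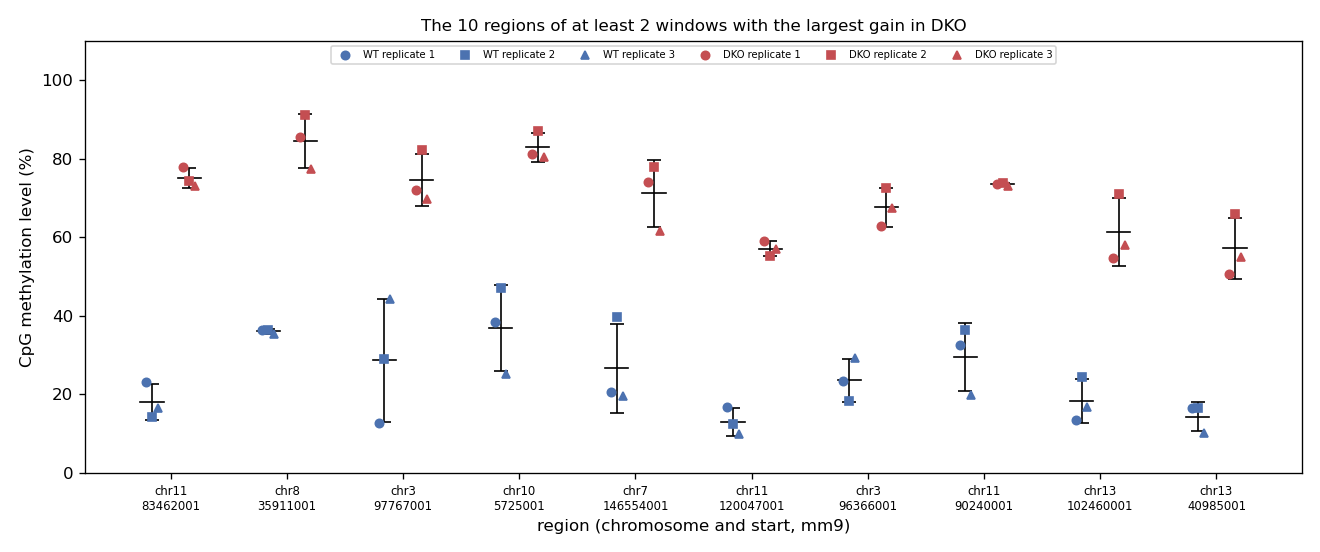
CpG methylation level (%) of the 10 regions in each sample, by chromosome and start (mm9), in the order of the difference between groups. Symbols are samples, horizontal lines are group means and bars are the SD (n = 3). The first region, on chromosome 11, goes from 18.0% in WT to 75.1% in DKO.

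The difference between groups varied with CpG density. Windows with 11 to 20 CpGs per kb had 85.6% ± 0.0499 in WT and 87.3% ± 0.233 in DKO (SD, n = 3 each), a difference of 1.71 points, and those with 21 to 40 had 72.5% ± 0.214 and 74.1% ± 0.0876, a difference of 1.55 points. The differences were 0.952 points at 6 to 10 CpGs per kb and 0.823 points above 40, where the WT level was 9.14% ± 0.356. Without high-copy windows, a setting added after the data were seen, the difference was 2.36 points at 21 to 40 CpGs per kb and 1.95 at 11 to 20, so the order of these classes depends on it. In the 4 classes from 6 CpGs per kb up, every DKO sample lay above every WT sample (two-sided exact permutation p = 0.1, the smallest possible). CpG-poor windows of all levels did not show this order. At 3 to 5 CpGs per kb the difference was 0.0675 points (exact permutation p = 1), and -0.401 points without DKO replicate 3. At 1 to 2 CpGs per kb, a class added after the data were seen, DKO replicates 1 and 2 had 85.5% and 85.8%, below the WT samples at 86.6% to 86.9%, and DKO replicate 3 had 87.5%, above them. Within the level classes of tested windows, a split added after the data were seen, windows with 3 to 10 CpGs per kb were higher in DKO too. Of the tested windows, 265545 had 6 to 10 CpGs, 9508 had 3 to 5 and 0 had 1 to 2. The split therefore says little about the CpG-poorest windows. In the 10 to 50% class the difference was 8.50 points at 3 to 10 CpGs per kb, 7.49 at 11 to 20, 4.16 at 21 to 40 and 2.32 above 40, where the WT levels also differed (31.2%, 29.9%, 24.9% and 18.2%). At 50 to 80% the differences were 5.30, 7.14, 6.88 and 4.16 points for the same densities, and at 80% or more 0.526, 0.966, 1.01 and 0.433 points, so the order of the densities differed between level classes. Below 10% they were 2.68, 2.41, 1.12 and 0.534 points, and in all 4 level classes and 4 density classes every DKO sample lay above every WT sample. The split-read check was not run within density classes. Counting error in the classing could therefore contribute to the differences between them.

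The same contrast appeared between 1 Mb bins. Of 2417 autosomal bins, 376 were higher and 3 lower in DKO (quasi-binomial test with limma-type moderation, adjusted p < 0.05). The largest gain was at chromosome 4, 134000001 to 135000000, from 71.9% ± 0.477 to 76.2% ± 0.568 (SD, n = 3). Next were chromosome 13, 37000001 to 38000000, from 80.1% ± 0.611 to 84.3% ± 0.691, and chromosome 7, 108000001 to 109000000, from 74.2% ± 0.434 to 78.4% ± 0.625. In the fifth of bins with the most CpGs, 236 of 484 bins were higher, and the mean level was 76.6% ± 0.332 in WT and 78.4% ± 0.712 in DKO (SD, n = 3; exact permutation p = 0.1). In the fifth with the fewest CpGs, 1 of 484 bins was higher and 1 lower; DKO replicates 1 and 2 were at 84.9% and 84.9%, below every WT sample (85.8% to 86.2%), and DKO replicate 3 was at 86.6%, above them. Across bins, which are not independent replicates, the difference rose with the number of CpGs (Spearman's rho = 0.741). The 3 bins called lower, on chromosome 9 at 35000001 and 3000001 and on chromosome 2 at 98000001, had 7.19, 73.5 and 117 times the median depth of all bins. The number of bins called was 134 and 245 without WT replicates 2 and 3, and 153, 832 and 87 without DKO replicates 1, 2 and 3. It was 678 with only CpGs in windows of fewer than 11 CpGs. With the replicate number as a block 673 bins were higher and 13 lower. Without high-copy windows, a setting added after the data were seen, 400 were higher and 0 lower.

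**Figure D4:**
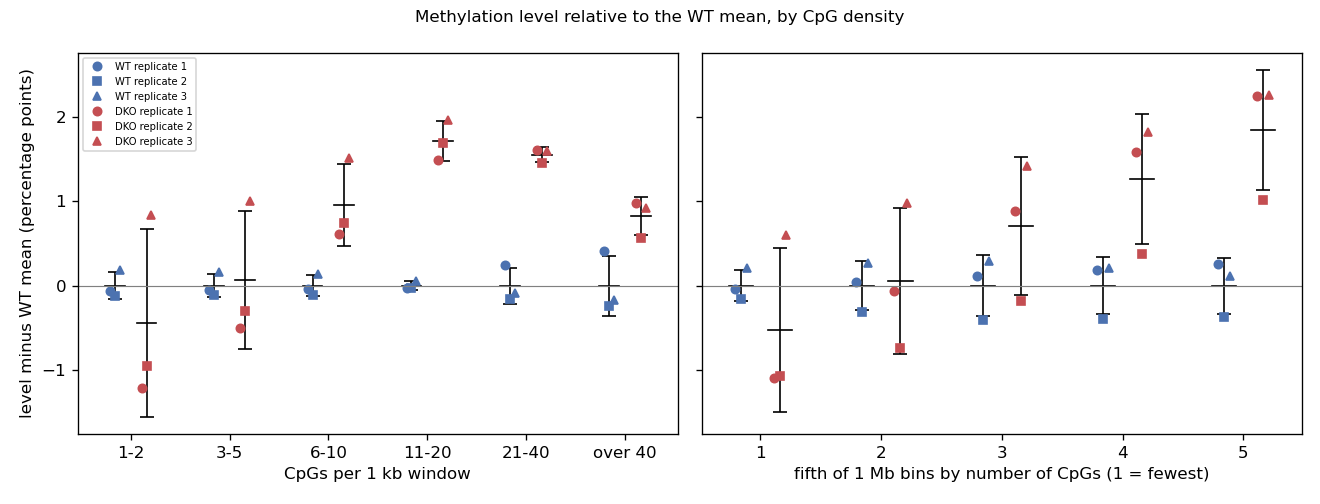
Methylation level of each sample minus the WT mean, in percentage points, by the number of CpGs per 1 kb window (left) and by the fifth of 1 Mb bins ranked by their number of CpGs (right). Symbols are samples, horizontal lines are group means and bars are the SD (n = 3). The DKO mean goes from -0.523 points in the CpG-poorest bins to 1.84 points in the CpG-richest.

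Complete switches of single CpGs were not detected at this depth. With at least 5 reads in every sample, 0 of 218834 autosomal CpGs were at 90% or more in every sample of a group and 10% or less in every sample of the other, which allows a share of up to 0.00137%. With at least 10 reads the count was 0 of 21112. These limits cover counting error only. They apply to the CpGs with that depth in every sample, at 5 reads 218834 of the 19595361 autosomal CpGs listed. They do not bound the share among the other CpGs. With reads pooled per group and at least 10 per group, which gives up the replicate check, 1437 of 8214526 CpGs were methylated only in DKO and 110 only in WT. The chromosomes with the lost segments did not stand out, with 65 of 445605 CpGs methylated only in DKO on chromosome 3 and 68 of 461675 on chromosome 6.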

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

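The settings without high-copy windows (over 3 times the median depth), with the same CpG weights in all samples, with reads thinned to equal depth, with split reads and with a dispersion prior from informative windows, and the class of 1 to 2 CpGs per kb, were chosen after seeing the data; the other alternatives were planned. The direction of the window calls held in every setting that made calls, while their number did not. Against 3854 calls, of which 98.5% were higher, leaving out each sample gave 29 to 749 calls (97.5% to 100% higher). A minimum of 10 reads gave 304 (99.7%), 40 reads 271 (99.3%) and Fisher's exact test on pooled reads 50074 (86.0%). The informative prior gave 8775 (96.8%). Centring gave 2650 calls, 98.0% higher, no minimum difference 97.3% higher, a minimum of 20 points 99.1% and 5 kb windows 95.9%. The 500 bp windows, limma, the replicate block and thinning gave 0 calls and so no share; at an unadjusted p of 0.05 they had 41408, 61094, 48161 and 65155 windows, of which 31966, 48611, 37721 and 49115 were higher. Leaving out a sample lowered the prior degrees of freedom from 23.7 to between 10.3 and 15.1, and thinning lowered them to 6.64. The number of calls did not simply follow them. They were 14.6 without WT replicate 1, with 435 calls, and 12.2 without DKO replicate 3, with 749 calls. The cause of the changed number of calls was not tested for any setting. The share of all tested windows that were higher, 58.2%, was 55.9% to 59.3% without each sample, 55.5% and 61.7% with 10 and 40 reads, 58.6% in 500 bp and 56.9% in 5 kb windows, 51.2% after centring and 54.6% (38.7% lower, the rest tied) after thinning. The global difference of 0.787 points was 1.48 and 0.142 points over CpGs with at least 5 and 10 reads, 0.882 over CpGs with a read in every sample, 0.992 with the same CpG weights and 0.941 without high-copy windows; the groups separated with 5 reads, with a read in every sample and with the same weights, and the cause was not tested. The 379 bins called at 1 Mb became 87 to 832 without each sample, 686 with the replicate block and 678 with only CpGs in windows of fewer than 11 CpGs; the cause was not tested. Without high-copy windows 400 bins were higher and 0 lower. The labels do not say whether equal replicate numbers pair the samples. Over 1 kb windows, deviations of same-numbered samples correlated at 0.0034, 0.0036 and 0.0033, each above every differently numbered pair (at most -0.0014). All these values are very small. Deviations were taken from the group mean and cancel within a group, so the order of the pairs is partly built in. The global level was lowest in replicate 2 and highest in replicate 3 in both groups, so pairing by number cannot be excluded. The class gains kept their direction in every setting: without each sample 0.713 to 0.925 points below 10%, and 5.90 to 6.78 at 10 to 50%; classing by WT replicate 1 alone gave 1.71, 7.41 and 4.52 points in the 3 lower classes, and split reads 6.03 at 50 to 80%. At 3 to 5 CpGs per kb the difference of 0.0675 points was -0.401 to 0.350 points without each sample and -0.00514 unweighted, so its sign is not set. Without high-copy windows the gain was 1.95 points at 11 to 20 CpGs per kb and 2.36 at 21 to 40, where the unweighted mean gave 1.98. In 500 bp windows the lost runs were 3 in place of 2, shorter and on the same chromosomes: 133132001 to 133133000 and 133133501 to 133134500 on chromosome 3, and 83352501 to 83353500 on chromosome 6. The count of switches stayed 0. Of 160 combinations of named region and setting, 97 kept a call and 63 lost it. Gene lists and genomic context were not run. Depth limited what could be said of single CpGs, since 218834 of 19595361 autosomal CpGs had at least 5 reads in every sample.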

Other observations

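Of the tests below, those of incomplete conversion, of the regrouped samples for the 1 kb windows and of an effect shared by all DKO samples were chosen after the result was seen. Thinning, split reads, equal CpG weights and the removal of high-copy windows were added after seeing the data, before their own values were seen.

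The difference between DKO and WT was larger at the edges of unmethylated regions than farther away, a hypothesis set before its values were seen. In 1290 runs of at least 3 adjacent windows below 10%, the level inside was 3.07% ± 0.169 in WT and 3.87% ± 0.171 in DKO (SD, n = 3). In the first 1 kb outside it was 43.6% ± 0.534 and 47.5% ± 0.363, a gain of 3.90 points, which was 3.36 points at 2 kb and 2.18 points at 10 kb. The gain in the first 1 kb exceeded that at 10 kb in each DKO sample, by at least 1.33 points. The window at 10 kb has a WT level of 80.8%, so the difference may come from the level itself rather than from the distance.

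Windows around 50% were a further group, since imprinted control regions, methylated on the allele of a single parent, are CpG-dense and lie there. Among windows at 35 to 65%, the 6286 with at least 21 CpGs per kb went from 46.5% ± 0.279 to 53.3% ± 0.516 (SD, n = 3), a gain of 6.77 points. The 31563 with 3 to 20 CpGs went from 48.4% ± 0.188 to 57.1% ± 0.428, a gain of 8.67 points. The gain of the CpG-dense windows was the smaller in every DKO sample, by at least 1.56 points (-1.56). It was smaller but present, so these windows as a set did not keep their WT level. The windows were chosen and measured on the same reads, and the split-read check was not run for this comparison. Counting error in the choice could therefore contribute to both gains and to the difference between them. Every sample lay at 35 to 65% in only 796 of the 6286 and 3119 of the 31563, so most were not at this level in each sample. How many are imprinted was not analysed here.

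The excess of windows higher in DKO was weighed against technical explanations. Correcting each sample by its mitochondrial rate left a gain of 6.02 points at 10 to 50% (6.24 before), which argues against incomplete conversion there, while below 10% the gain fell from 0.856 to 0.434 points. Depth cannot move the expected level of a window but can move its class. Classing on equally thinned calls left 6.17 points at 10 to 50%. Measuring on calls not used for classing left 6.06 points there and 6.03 at 50 to 80%. For calls taken as independent, this argues against unequal counting error in the classing. Calls of the same read at several CpGs could fall in both parts, so error shared within reads is not excluded. Giving each CpG the same weight in all samples left a median of 27.3 points in the windows called higher, which argues against uneven coverage, while the number of calls cannot be told apart from depth, since thinning ended all calls with a median of 30 points in those windows. The real grouping gave 3854 calls and 1 of 10 splits reached that number, with at most 1 call in any other; for 1 Mb bins 1 of 10 splits reached the 379 real calls, with at most 0 in any other, and 10 splits are too few for a share under 0.05; loss of Tet2 and Tet3, and a different mix of cells within the sorted fraction, stay open as untested.

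The 56 windows called lower lay in CpG-dense sequence, with a median of 29 CpGs against 16 in the windows called higher. With the same CpG weights in all samples their median difference shrank from -20.2 to -9.30 points. The groups were apart in 22 of 55, against 49 with each sample's own reads. Of the windows called higher the groups were apart in 3165 of 3773, against 3712 with own reads. In the windows called lower the ratio of DKO to WT reads was 1.22 times that of windows with the same number of CpGs. Depth thus differed more between the groups here than in such windows. A larger difference in depth does not exclude depth as a cause, so this ratio cannot decide it. The values are consistent with uneven recovery of methylated and unmethylated CpGs within a window as a cause of much of this loss.

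CpG-poor 1 Mb bins were lower in DKO replicates 1 and 2 than in any WT sample. The difference of these samples from the WT mean was -1.09 points without high-copy windows and -0.920 points with the same CpG weights, so neither high-copy sequence nor uneven coverage accounts for it. DKO replicate 3 was 0.601 points above the WT mean, but the pattern was noticed from that value and rests on this sample, so whether the genotype has an effect shared by all DKO samples cannot be told apart from differences between samples. A difference between animals, between stages of a change in the DKO cells or between libraries stays open, and the labels give no batch, age or disease stage that would separate these.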
